A study of Mus musculus with 4 samples.

How the data were processed

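RNA from 4 samples of sorted mouse prostate stromal cells, 2 from proximal and 2 from distal ducts, was measured by sequencing. Per the labels' protocols, total RNA was converted to cDNA with the SMART-Seq v4 ultra low input kit using random and oligo-dT primers, made into libraries with the TruSeq DNA kit and sequenced on an Illumina HiSeq instrument. This kit amplifies cDNA by PCR and does not mark strand, so overlapping genes and antisense partners cannot be told apart. Per the submitters' processing notes, bcl2fastq 1.8.3, TopHat2 0.6 and Cufflinks 0.0.6 were used with the mm10 genome; the last 2 versions look like those of a workflow wrapper. The role and order of these tools are not given in the sources used here.

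The deposited files give FPKM per transcript, with lower and upper FPKM bounds, a coverage signal and an estimate status, per the file headers. Each lists 63241 transcripts by identifier and position. FPKM is scaled by transcript length and by mapped fragments, so it holds no counts and a count model was not used. Cufflinks divides fragments among overlapping transcripts, so near-identical copies share values and an exact 0 need not mean a silent gene. Total fragments are not given in the sources used here, so absolute depth is unknown. The deposited coverage signal per FPKM, which scales with depth at equal read length, had medians of 5.69 (distal 2), 6.36 (distal 3), 5.23 (proximal 2) and 5.39 (proximal 3). The deposited bounds had a median half-width of 13.8% to 14.8% of the value for transcripts of 1 to 10 FPKM, 6.4% to 7.1% from 10 to 100 FPKM and 4.4% to 4.5% from 100 to 1000 FPKM. PCR copies are not independent molecules, so these bounds cover the authors' estimation error within a library only.

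The files pair no gene symbol with a transcript. Transcripts were named by position against GENCODE M21, which uses the same assembly. A transcript took a gene's name where span overlap times length similarity with one of its annotated transcripts reached 0.8 and no other gene came within 0.8 of that score. Otherwise both of its ends had to lie within 100 bp of exons of one gene, or it had to overlap one gene with a similarity of at least 0.5 while any other stayed under 0.25. This named 55415 transcripts (87.63%), which held 96.32% of the summed FPKM, in 25576 genes. Of the transcripts with a mean of at least 1 FPKM named by span and length, 12402 lay in the RefSeq gene of the same name, 43 in another and 117 in none. FPKM was then summed per gene. Coordinates are 1-based, from that annotation.

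Genes with a failed or capped estimate in any library (7 at the same minimum) and unnamed features (257 at the same minimum) were left out. A gene was tested if it reached 1 FPKM in at least 2 of the 4 libraries. Values were tested as log2(FPKM + 1), so fold changes understate the change of low genes. The test was limma 3.58.1 in R 4.3.3 (linear model with region as the only term, empirical Bayes with a mean trend), two-sided, with Benjamini-Hochberg adjustment over 11249 genes and a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for naming, checks and plots.

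The design, 36 gene lists and most alternatives were fixed before the data were examined. The lists cover Wnt, TGF-beta, BMP, Hedgehog, Notch, kinase ligand, retinoic acid and steroid signalling, transcription factors, matrix, muscle, fibroblast, stress, inflammation, interferon, cell cycle, mitochondrial and ribosomal genes and other cell types. Lists with at least 3 tested members (35 of them) were tested with camera at its preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry beside it. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Of 4 lists called at the preset correlation, 0 were called with an estimated correlation (smallest adjusted p = 0.731) and 0 by fry for one direction (smallest adjusted p = 0.928). Camera with an estimated correlation works with the few residual degrees of freedom of 4 libraries. Its adjusted p was 0.731 even for Schwann cells and neurons, whose estimated correlation of -0.152 lay below the preset 0.01. Failing it is therefore weak evidence against a call, here and below.

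The text names up to 12 genes per direction. These had the largest change among called genes with non-overlapping regions and a mean of at least 5 FPKM in the higher region, and with 0 called genes the 12 with the smallest unadjusted p took their place. It also names the sort markers, the 10 most abundant genes and, per list, called members or the 3 with the largest difference. Genes outside this rule are said to be chosen after their values were seen.

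The fit was tested on simulated data for proximal against distal over 11249 genes, in 10 draws of 200 changed genes. With independent spread it recovered 0% of 2-fold, 0.4% of 4-fold and 38.2% of 16-fold changes, and 7.1% of its calls were false. A first version of this simulation took each gene's sample variance as its true variance and recovered 0% at every size. It was replaced because sample variances on few degrees of freedom count sampling noise a further time, lowering the prior degrees of freedom from 3.24 in the data to 1.52; true variances are now drawn from the fitted prior. Fitted differences were centred on the simulated ones in both versions. A list of 25 genes shifted by 1 on the log2 scale was found by camera (unadjusted p under 0.05) in 100% of 50 draws, and an unshifted one in 4%. Genes in these draws were independent and had no difference between numbers, and their spread was that of the fit with the number as a block. The 4% therefore does not give the rate of false calls for the real lists, nor the 100% the rate at which real shifts are found. Estimated correlations in the 4 called lists ran from -0.152 (Schwann cells and neurons) to 0.849 (ribosomal proteins).

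Alternatives were another pseudocount, filter, scaling, variance model, feature or list test, failed estimates kept, the replicate number as a block, and each library left out. Leaving out genes listed at 0 in any library, and keeping unnamed transcripts, were added after seeing the data. 2 tests of explanations were changed after their values were seen. The first depth test asked whether coverage per FPKM separated the numbers, which it did not (gap -0.297); it was replaced because number 3 was higher within each region, so that overlap could not exclude depth. A second one compared the correlation of proximal 2 and proximal 3 with that of distal 3 and proximal 3 (difference -0.083) and was replaced as well, because those correlations are the pattern to be explained. The third, a slope between the regions' number differences, was also chosen with the values known. The ratio of proximal 3 to proximal 2 in named genes was first read as arguing against carried-over epithelium and is now left undecided, because those genes were picked by p.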

Results

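RNA of prostate stromal cells from adult C57BL/6 mice was compared between the 2 ends of the ductal tree. The proximal ducts lie next to the urethra and the distal ducts end at the tips of the lobes. Stromal cells were sorted by flow cytometry as negative for lineage markers (not listed in the labels), CD24 and CD49f and positive for Sca-1, a surface protein of mesenchymal progenitors and fibroblasts. The stated purpose was to identify signalling in this stroma. There were 2 libraries per region, numbered 2 and 3 in both, and they are called distal 2, distal 3, proximal 2 and proximal 3 here. The values are transcript FPKM (fragments scaled by transcript length and by mapped fragments), summed here per gene. Between 10137 genes (distal 3) and 11436 genes (proximal 2) reached 1 FPKM, and 11249 genes entered the comparison. No label says whether the libraries came from separate animals, so every p-value measures only the spread between these libraries, which may be technical.

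Values of sort marker genes were read from all 4 libraries, except for Ly76, chosen to stand for a lineage marker, which matched no named gene. Ly6a, which encodes Sca-1, stood at 1016 and 868 FPKM in distal 2 and distal 3 and at 687 and 738 FPKM in proximal 2 and proximal 3. Itga6, which encodes CD49f, did not exceed 1.34 FPKM, the endothelial marker Pecam1 did not exceed 1.56 FPKM, and the leukocyte marker Ptprc did not exceed 0.120 FPKM, each highest in proximal 3. Cd24a, which encodes CD24, was measured at 9.64 and 19.1 FPKM in the distal libraries and at 8.06 and 54.6 FPKM in proximal 2 and proximal 3. Both proximal values of Ly6a lay below both distal values. Neither Ly6a nor Cd24a passed the test (both adjusted p = 0.99991, limma).

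The most abundant transcripts included metal-binding, matrix, heat shock and immediate early genes. The metallothioneins Mt1 and Mt2 averaged 9190 and 5483 FPKM over the 4 libraries, the actin-severing protein gelsolin (Gsn) 7297 FPKM, matrix Gla protein (Mgp) 3666 FPKM and decorin (Dcn), a collagen-binding proteoglycan, 2842 FPKM. Ubiquitin B (Ubb, 3347 FPKM), the heat shock genes Hspa1b (3206 FPKM) and Hspa1a (2832 FPKM), proenkephalin (Penk, 2869 FPKM) and the immediate early gene Junb (2695 FPKM) completed the first 10. Penk averaged 4070 ± 1075 FPKM in distal and 1668 ± 959 FPKM in proximal stroma (SD, n = 2 each).

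The genes with the smallest p and higher proximal values included Lgr5, Ptgds, Vtn, Epha3 and Cxcl12. Lgr5, the R-spondin receptor known from stem cells of several epithelia, averaged 79.3 ± 40.1 FPKM in proximal and 1.43 ± 0.991 FPKM in distal stroma (SD, n = 2 each), a log2 difference of 5.01 ± 0.55 (SE). The log2 difference was 4.91 within the libraries numbered 2 and 5.12 within those numbered 3. Cxcl12, the chemokine ligand of CXCR4, averaged 662 ± 121 FPKM against 94.0 ± 33.2 FPKM, a log2 difference of 2.84 ± 0.38 (SE). Prostaglandin D synthase (Ptgds) averaged 44.2 ± 6.22 against 0.832 ± 0.569 FPKM, vitronectin (Vtn) 24.5 ± 3.73 against 1.62 ± 0.139 FPKM, and the ephrin receptor Epha3 9.34 ± 0.200 against 0.129 ± 0.0507 FPKM. The tetraspanin Tspan8 averaged 42.4 ± 21.7 against 0.324 ± 0.0272 FPKM. Sprr2a1 and Sprr2a2, which encode cornified envelope proteins, averaged 56.2 ± 24.9 and 56.0 ± 24.6 FPKM in proximal stroma and 0.863 ± 0.497 and 0.361 ± 0.146 FPKM in distal stroma, but these are near-identical neighbouring copies whose fragments the quantification could divide in any way, so their separate values are uncertain. Lgr5 lies on chromosome 10 at 115450311 to 115587780 (minus strand, mm10), Cxcl12 on chromosome 6 at 117168535 to 117181367 (plus strand) and Ptgds on chromosome 2 at 25466709 to 25470046 (minus strand).

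The genes with the smallest p and higher distal values included Saa3, Ren1, Crym and Tslp. The acute phase protein gene Saa3 averaged 61.0 ± 28.5 FPKM in distal and 7.30 ± 0.441 FPKM in proximal stroma (SD, n = 2 each), a log2 difference of -2.82 ± 0.44 (SE), and its neighbour Saa1 6.13 ± 0.779 against 0.419 ± 0.347 FPKM. Renin (Ren1), the enzyme that cleaves angiotensinogen, averaged 17.8 ± 1.21 against 1.70 ± 1.30 FPKM, a log2 difference of -2.89 ± 0.50 (SE). The epithelium-associated cytokine Tslp averaged 17.0 ± 4.49 against 2.79 ± 0.268 FPKM, the relaxin receptor Rxfp1 13.7 ± 1.24 against 2.28 ± 1.35 FPKM and the sphingosine phosphate receptor S1pr1 7.16 ± 0.303 against 1.28 ± 0.601 FPKM. Crym, which binds thyroid hormone, averaged 24.4 ± 2.88 against 4.98 ± 0.497 FPKM, Btbd3 35.1 ± 10.2 against 8.39 ± 1.84 FPKM, C1qtnf3 28.6 ± 8.80 against 7.69 ± 0.322 FPKM, Dmkn 7.42 ± 2.86 against 1.05 ± 0.392 FPKM and 9530003J23Rik 6.73 ± 1.33 against 0.942 ± 0.293 FPKM. Saa3 lies on chromosome 7 at 46711998 to 46715700 (minus strand, mm10) and Ren1 on chromosome 1 at 133350510 to 133360325 (plus strand).

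**Figure D1:**
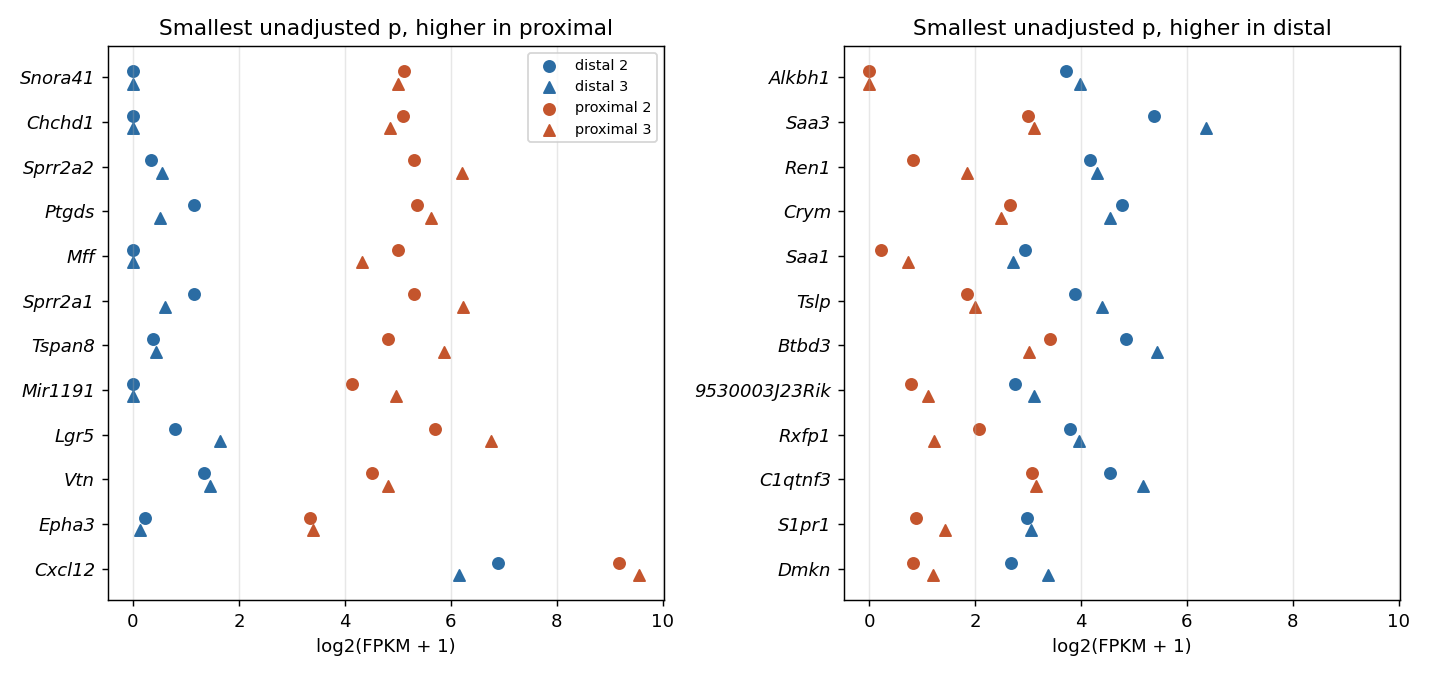
Gene levels as log2(FPKM + 1) on the horizontal axis, 1 row per gene and 1 point per library (blue distal, orange proximal, circles for number 2 and triangles for number 3). In each row both libraries of one region lie beyond both of the other, because the genes were chosen that way. For Cxcl12 the distal libraries sit at 117 and 70.5 FPKM and the proximal libraries at 577 and 748 FPKM.

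None of these genes passed the test, which had region as its only term. With the library number as a block, 440 genes passed (limma), among them all 24 genes named for the smallest p. Those 24 were picked from the same libraries for a small p, so their passing was partly built in. No label says that a number marks a shared animal or day, so that fit is an alternative only. The limma fit called 0 genes higher in proximal and 0 genes higher in distal stroma, with a smallest adjusted p of 0.197. An unadjusted p under 0.05 was reached by 252 genes with higher proximal and 102 genes with higher distal values, together 354 genes where chance alone gives about 562 if the libraries are independent. Both proximal libraries lay above both distal libraries for 1453 genes and below them for 973 genes, 21.6% of genes against the 33.3% that random order of independent libraries gives. Of the genes at an unadjusted p under 0.05, 71.2% were higher in proximal stroma, against 60.4% of all tested genes. Under quantile normalization, which moved the median of all genes by -0.12 on the log2 scale from 0.09, these shares were 61.1% and 46.8%. In simulated data with the spread of these libraries, shared by number as here, the same fit recovered 0% of 2-fold, 0% of 4-fold and 5.2% of 16-fold changes, so a call of 0 does not exclude large differences.

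The 4 libraries were more alike by number than by region. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.953 between distal 2 and proximal 2 and 0.952 between distal 3 and proximal 3, against 0.911 between the distal libraries and 0.869 between the proximal libraries. The difference between regions had the same sign within both numbers for 67.0% of genes. It was at least 2-fold in both numbers for 213 genes with higher proximal values and for 87 genes with higher distal values. These comparisons of 1 library with 1 library carry no test. A fit that leaves out 1 library keeps only 1 number in 1 region, so its region difference takes in part of the difference between numbers. List results from such fits, given below, therefore mix region with number and are no calls for a region.

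**Figure D2:**
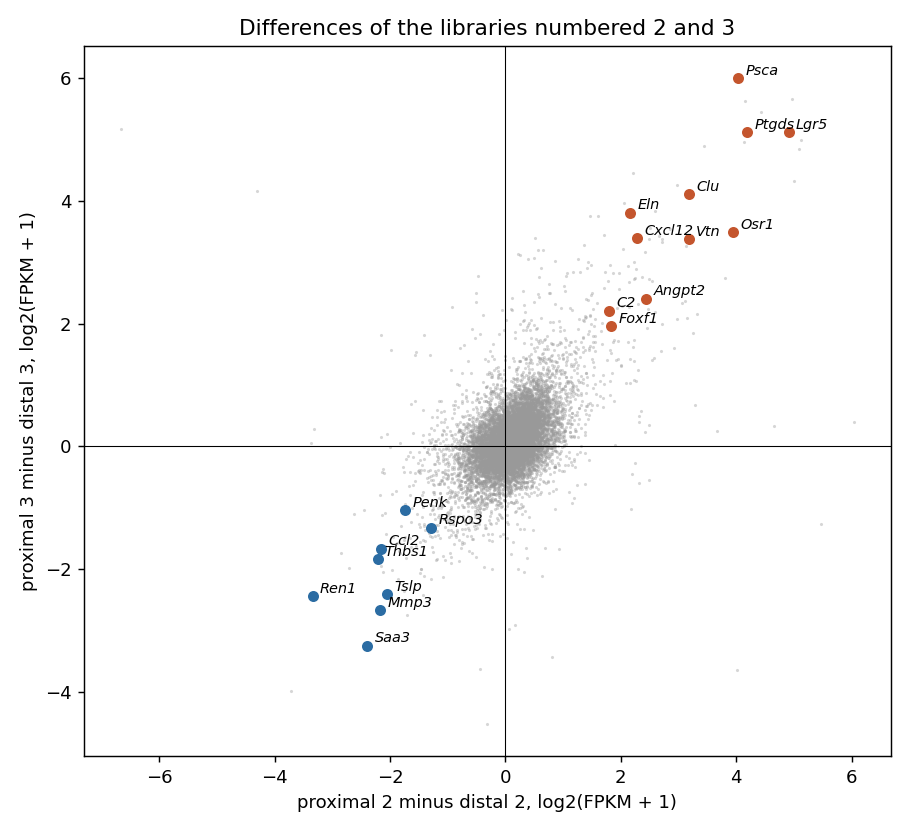
Log2(FPKM + 1) difference of proximal 2 minus distal 2 (horizontal axis) against proximal 3 minus distal 3 (vertical axis), 1 point per tested gene, with 19 genes marked after their values were seen (orange higher in proximal, blue higher in distal). Lgr5 lies at 4.91 and 5.12 and Thbs1 at -2.22 and -1.84.

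Another 4 of the genes with higher proximal values and 1 with higher distal values were listed at exactly 0 in both libraries of the other region. Chchd1, a mitochondrial ribosome component, was listed at 0 in distal 2 and distal 3 and at 33.2 and 27.8 FPKM in proximal 2 and proximal 3. Mff, a mitochondrial fission factor, was listed at 0 in both distal libraries and at 31.1 and 19.1 FPKM in the proximal libraries, and the small RNA genes Snora41 and Mir1191 were likewise at 0 against 33.9 and 30.8 FPKM and against 16.5 and 30.1 FPKM. Alkbh1 was at 12.2 and 14.9 FPKM in distal 2 and distal 3 and listed at 0 in the proximal libraries. Genes that every cell uses, such as Polr2b and Rpl31 (chosen after their values were seen), were listed at 0 in both libraries numbered 2, so a listed 0 need not mean a silent gene. The genes of this paragraph had no failed or capped status in any library, since genes with one were left out.

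Of 9 tested Wnt ligands 8 had higher proximal values, as did 60.4% of all tested genes, and 1 a higher distal value, Wnt11 (chosen after its values were seen). In this list 0 genes passed over all genes and 0 passed adjusted over the list alone. Adjustment over a list alone takes no account of the other lists, here and below, so a pass of that kind is weak. Wnt5a, a non-canonical ligand, stood at 28.3 and 12.4 FPKM in proximal 2 and proximal 3 and at 9.14 and 4.44 FPKM in distal 2 and distal 3, and Wnt4 at 13.4 and 2.43 FPKM against 2.57 and 0.373 FPKM. The median log2 difference of the ligands was 0.45 and the list did not pass the test (camera adjusted p = 0.158). With 1 library left out the median was 1.10 without distal replicate 2 and 1.25 without proximal replicate 3. It was -0.06 without distal replicate 3 and -0.32 without proximal replicate 2. These shifts mix region with number: the ligands' median difference of number 3 minus number 2 was -1.29. Among 16 Wnt receptors and R-spondins, 1 gene passed when adjusted over the list alone, Lgr5 (adjusted p = 0.00332, limma), and 0 passed over all genes. Rspo1 stood at 3.57 and 2.83 FPKM in proximal against 0.661 and 0.233 FPKM in distal stroma, while Rspo3 stood at 19.8 and 10.1 FPKM against 49.7 and 27.0 FPKM, with a log2 difference of -1.31 ± 0.50 (SE). The list's median was 0.07 (camera adjusted p = 0.662), and -0.09 under quantile normalization. With 1 library left out it ranged from -0.44 (without proximal replicate 2) to 0.39 (without proximal replicate 3).

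Secreted Wnt inhibitors and Wnt response genes gave no call over all genes. Of 9 inhibitors, Dkk2 stood at 44.5 and 10.3 FPKM in proximal 2 and proximal 3 against 9.18 and 3.21 FPKM in distal 2 and distal 3, Sfrp4 at 6.07 and 12.4 against 1.54 and 2.35 FPKM, and Sfrp2 at 309 and 263 against 206 and 81.3 FPKM (list median 0.17, camera adjusted p = 0.482, 0 passing over the list alone). Of 18 canonical response genes, Lgr5 again was the 1 to pass over the list alone, and Rnf43, a membrane ubiquitin ligase that removes Frizzled receptors, stood at 5.63 and 2.49 FPKM in proximal against 0.427 and 0.138 FPKM in distal stroma. Tnfrsf19 stood at 14.04 and 2.93 against 21.5 and 12.1 FPKM. The median of the response genes was -0.005 with a mean of 0.26, and camera gave an adjusted p of 0.861 toward proximal. With 1 library left out, the median of the response genes ranged from -0.75 (without proximal replicate 2) to 0.50 (without distal replicate 2), and that of the inhibitors from -0.14 (without proximal replicate 2) to 0.50 (without proximal replicate 3).

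TGF-beta and BMP genes also went both ways. Of 22 TGF-beta ligands, receptors and modulators, thrombospondin 1 (Thbs1), which activates latent TGF-beta, averaged 2187 FPKM in distal and 568 FPKM in proximal stroma, a log2 difference of -2.03 ± 0.70 (SE), while Tgfb2 stood at 8.37 and 28.2 FPKM in proximal against 2.38 and 5.66 FPKM in distal libraries and Ltbp1 at 10.7 and 15.4 against 4.99 and 7.58 FPKM. The list's median was 0.01, below 0 under quantile normalization and median ratio scaling, and camera pointed to distal (adjusted p = 0.744). Of 20 TGF-beta response genes, elastin (Eln) stood at 282 and 247 FPKM in proximal against 61.9 and 16.8 FPKM in distal libraries and Tgfbi at 14.9 and 18.2 against 4.85 and 5.45 FPKM, with a list median of -0.06, a mean of 0.06 and a camera adjusted p of 0.903 toward distal. Of 18 BMP genes, Gdf10 stood at 275 and 186 FPKM in proximal against 107 and 53.7 FPKM in distal libraries and Bmp4 at 110 and 72.9 against 55.5 and 38.4 FPKM (median 0.12, camera adjusted p = 0.806). In these 3 lists 0 genes passed over all genes and 0 passed over the list alone. With 1 library left out, the medians ranged from -0.02 (without proximal replicate 2) to 0.08 (without distal replicate 2) for the TGF-beta ligands, receptors and modulators, from -0.20 (without distal replicate 3) to 0.22 (without distal replicate 2) for the TGF-beta response genes and from -0.19 (without distal replicate 3) to 0.39 (without proximal replicate 3) for the BMP genes.

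In the remaining signalling lists 0 genes passed over all genes. Of 11 Hedgehog pathway genes, the forkhead factor Foxf1 passed over the list alone (adjusted p = 0.0322, limma), at 47.1 and 65.5 FPKM in proximal against 12.5 and 16.2 FPKM in distal libraries, while Hhip and Ptch1 had log2 differences of 0.52 ± 0.36 and 0.50 ± 0.49 (SE). Of 26 ligands of receptor tyrosine kinases, Angpt2, a ligand of the endothelial receptor Tie2, passed over the list alone (adjusted p = 0.0415, limma), at 5.12 and 6.54 FPKM in proximal against 0.127 and 0.428 FPKM in distal libraries, and Fgf7, a mitogen of epithelia, stood at 29.2 and 50.2 against 10.8 and 11.5 FPKM. Of 11 Notch genes, Hey1 stood at 6.77 and 9.87 against 2.37 and 2.29 FPKM. Of 14 retinoic acid genes, Rdh10, which oxidises retinol, stood at 52.1 and 110 FPKM in proximal against 150 and 268 FPKM in distal libraries. Of 12 steroid receptor and androgen-responsive genes, Zbtb16 had a log2 difference of 1.07 ± 0.66 (SE). Adjusted over the list alone, 0 Notch, 0 retinoic acid and 0 steroid genes passed. The camera adjusted p was 0.607 for Hedgehog, 0.482 for the kinase ligands, 0.744 for Notch, 0.968 for retinoic acid and 0.540 for steroid genes, with medians of 0.06, 0.09, 0.09, 0.17 and 0.25. The medians of the Hedgehog, kinase ligand and Notch lists were below 0 under quantile normalization, and camera pointed to distal for retinoic acid. With 1 library left out, the medians ranged from -0.39 to 0.50 for Hedgehog and from -0.07 to 0.60 for steroid genes (both lowest without proximal replicate 2 and highest without distal replicate 2), from -0.05 (without proximal replicate 3) to 0.36 (without distal replicate 2) for the kinase ligands, and from 0.04 to 0.66 for Notch and -0.14 to 0.40 for retinoic acid (both lowest without proximal replicate 2 and highest without proximal replicate 3).

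Mesenchymal transcription factors included 2 genes that passed over the list alone among 28 tested, with 0 passing over all genes. Osr1, a regulator of urogenital mesenchyme, stood at 99.4 and 34.0 FPKM in proximal 2 and proximal 3 and at 5.51 and 2.12 FPKM in distal 2 and distal 3, a log2 difference of 3.72 ± 0.67 (SE; adjusted p over the list alone = 0.0410, limma). Foxf1 gave the same adjusted p over that list, 0.0410 (limma). Its relative Foxf2 stood at 6.71 and 1.77 against 0.817 and 0.352 FPKM. The list's median was 0.17 (camera adjusted p = 0.246). With 1 library left out, which mixes region with number, the median was 0.62 without distal replicate 2 and 0.65 without proximal replicate 3. It was -0.27 without distal replicate 3 and -0.10 without proximal replicate 2. Of 10 tested Hox genes none passed either way. Hoxa13 stood at 17.3 and 32.5 FPKM in the libraries numbered 2 of distal and proximal stroma and at 0.655 and 1.20 FPKM in those numbered 3 (list median 0.23, camera adjusted p = 0.607). With 1 library left out, which mixes region with number, the Hox median was 0.81 without distal replicate 2 and 0.997 without proximal replicate 3. It was -0.24 without distal replicate 3 and 0.08 without proximal replicate 2. The Hox list's median difference of number 3 minus number 2 was -1.10.

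Of the matrix genes none passed over all genes or over a list alone. Of 38 fibrillar collagen and matrix genes, Fbln1 stood at 172 and 204 FPKM in proximal against 94.4 and 92.8 FPKM in distal libraries and fibronectin (Fn1) at 6.43 and 12.4 against 13.8 and 28.2 FPKM (median -0.09, camera adjusted p = 0.108). The collagen list passed toward distal with no filter (adjusted p = 0.0429), without distal replicate 2 (median -0.10, adjusted p = 0.0488) and without proximal replicate 3 (median 0.01, adjusted p = 0.0350). Of 21 basement membrane genes, Col4a3 stood at 15.4 and 5.66 against 39.0 and 28.7 FPKM and Col18a1 at 65.5 and 77.8 against 39.5 and 40.0 FPKM (median -0.03, camera adjusted p = 0.287; -0.23 without distal replicate 2, which passed with an adjusted p of 0.0342). Of 27 matrix remodelling genes, the metalloproteinase Mmp3 stood at 7.004 and 15.3 against 35.1 and 103 FPKM, and Adamts4, an aggrecanase, at 108 and 285 against 478 and 620 FPKM. The remodelling median was 0.01 with a mean of -0.24, negative medians under quantile normalization and median ratio scaling, and a camera adjusted p of 0.0657 toward distal. It passed toward distal without distal replicate 2 (median -0.15, adjusted p = 0.00132) and without proximal replicate 3 (median -0.13, adjusted p = 0.000939). Of 19 smooth muscle genes, Myh11 stood at 12.3 and 5.32 against 5.11 and 2.79 FPKM and Actg2 at 3.42 and 0.862 against 6.87 and 3.82 FPKM (median -0.16, camera adjusted p = 0.287). The smooth muscle median was -0.39 without proximal replicate 2 (adjusted p = 0.0602) and 0.004 without proximal replicate 3. Of 25 fibroblast genes, Mfap4, a microfibril protein, stood at 229 and 352 against 86.1 and 65.9 FPKM and Dpt at 132 and 375 against 64.4 and 99.9 FPKM (median -0.02, mean 0.13, camera adjusted p = 0.750 toward proximal; -0.07 without distal replicate 3 and 0.25 without proximal replicate 3).

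The list of chemokines, cytokines and prostaglandin synthesis lay lower in proximal stroma than other genes did (26 genes, median log2 difference -0.56, camera adjusted p = 4.65e-05). This call did not hold with an estimated correlation (camera adjusted p = 0.731). It held with the library number as a block (camera adjusted p = 1.79e-06), an alternative only. With 1 library left out, which mixes region with number, the median was -0.19 without distal replicate 3 and -0.06 without proximal replicate 2. It was -0.90 without distal replicate 2 and -1.35 without proximal replicate 3. The list's median difference of number 3 minus number 2 was 0.716. The median was -0.70 within number 2 and -0.38 within number 3. The monocyte chemokine Ccl2 stood at 1261 and 2207 FPKM in distal 2 and distal 3 and at 284 and 693 FPKM in proximal 2 and proximal 3, and the neutrophil chemokine Cxcl2 at 24.9 and 153 against 6.67 and 28.9 FPKM (Ccl2 was chosen after its values were seen). Over the list alone 2 genes passed, in opposite directions: Cxcl12 (adjusted p = 0.0153, limma) with higher proximal and Tslp (adjusted p = 0.0342, limma) with higher distal values. Of 14 complement genes, 3 passed over the list alone, each with higher proximal values: clusterin (Clu) at 54.9 and 203 FPKM against 5.15 and 10.9 FPKM, C2 at 87.0 and 111 against 24.2 and 23.3 FPKM, and Masp1 at 82.7 and 88.2 against 35.0 and 30.1 FPKM. The complement list had a median of -0.03 and a mean of 0.42 (camera adjusted p = 0.540 toward proximal), and passed toward proximal without distal replicate 3 (median 0.03, adjusted p = 0.0315) and without proximal replicate 2 (median 0.06, adjusted p = 0.0491).

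Interferon, immediate early, cell cycle, mitochondrial and ribosomal genes were tested as further lists, with 0 genes passing over all genes or over any of these lists alone. The 26 interferon response genes had a median of 0.12 (camera adjusted p = 0.750), with Psmb9 at 7.90 and 6.10 FPKM in proximal against 2.97 and 2.62 FPKM in distal libraries. With 1 library left out, which mixes region with number, the interferon median was 0.90 without distal replicate 3 and 0.83 without proximal replicate 2. It was -0.62 without distal replicate 2 and -0.78 without proximal replicate 3. The list's median difference of number 3 minus number 2 was 1.445. The 33 immediate early and stress genes had a median of 0.34 (camera adjusted p = 0.287), and Fosb stood at 385 and 459 against 235 and 201 FPKM. They passed under quantile normalization (adjusted p = 0.0420) and without distal replicate 2 (median 0.74, adjusted p = 0.0456), and had a median of -0.10 without distal replicate 3. The 17 cell cycle genes had a median of 0.01 (camera adjusted p = 0.744), negative under quantile normalization and median ratio scaling, -0.06 without distal replicate 2 and 0.19 without proximal replicate 2. The 6 mitochondrial genes had one of 0.20 (camera adjusted p = 0.607). With 1 library left out, the mitochondrial median ranged from -0.03 (without proximal replicate 3) to 0.30 (without proximal replicate 2). The 33 ribosomal protein genes lay lower in proximal stroma (median -0.18, camera adjusted p = 0.00662). The call did not hold with an estimated correlation (camera adjusted p = 0.918). It held with the library number as a block (camera adjusted p = 0.00669), an alternative only. With 1 library left out, which mixes region with number, the median was -0.22 without distal replicate 3 and 0.10 without proximal replicate 2. The median was -0.46 without proximal replicate 3, and the median was -0.45 within number 2 and 0.12 within number 3.

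Transcripts of basal and urethral-type epithelium lay higher in proximal libraries (14 genes, median 1.62, camera adjusted p = 5.77e-07; 1.23 within number 2 and 1.79 within number 3). The call did not hold with an estimated correlation (camera adjusted p = 0.918). It held with the library number as a block (camera adjusted p = 4.72e-05), an alternative only. Without proximal replicate 3, in a fit that mixes region with number, the median was 0.81. Camera, which compares with all other genes, pointed to distal in that fit. The median was 1.03 without distal replicate 2 and 2.59 without distal replicate 3. The call held, at medians of 0.58 with no filter, 0.78 at a pseudocount of 5 and 0.98 with genes listed at 0 left out. Over the list alone 2 genes passed, Psca and Krt4 (both adjusted p = 0.00814, limma). Psca stood at 15.4 and 65.7 FPKM in proximal 2 and proximal 3 and at 0 and 0.0441 FPKM in distal 2 and distal 3, and Krt7 at 5.07 and 33.8 against 0.307 and 0.590 FPKM. The 22 luminal epithelium genes had a median of 0.68 (camera adjusted p = 0.169). They passed toward proximal without distal replicate 3 (median 0.98, adjusted p = 1.16e-07) and without proximal replicate 2 (median 1.12, adjusted p = 1.50e-12), and toward distal without proximal replicate 3 (median 0.06, adjusted p = 0.0133). Of these, 3 passed over the list alone, Crym and 9530003J23Rik with higher distal values and Msmb, listed at 0 in both distal libraries and at 1.76 and 3.34 FPKM in the proximal ones. The 6 mesothelium genes, which include the keratins Krt8, Krt18 and Krt19, had a median of 1.08 (camera adjusted p = 0.0657), which was 0.20 without proximal replicate 3. The mesothelium median was 1.59 without distal replicate 3 and 1.87 without proximal replicate 2, in fits that mix region with number. Nkain4 passed over the list alone, at 4.84 and 12.1 against 0.217 and 0.773 FPKM.

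Of the other cell type lists, 1 passed the test. The 5 Schwann cell and neuron genes lay lower in proximal stroma (median -0.67, camera adjusted p = 0.00371), with Uchl1 at 3.47 and 6.17 FPKM in proximal against 8.64 and 13.4 FPKM in distal libraries. That call did not hold with an estimated correlation (camera adjusted p = 0.731), although that correlation, -0.152, lay below the preset 0.01. Nor did it hold with no filter on low values (median 0.06, camera adjusted p = 0.959). It held with the library number as a block (camera adjusted p = 0.00356), an alternative only. The medians without distal replicate 3 and without proximal replicate 2, -0.77 and -0.72, were no smaller in size. At a pseudocount of 5 the median was -0.33. The 8 leukocyte genes had a median of -0.20 (camera adjusted p = 0.0657). They passed toward distal at a pseudocount of 0.1 (adjusted p = 0.0369), under quantile normalization (median -0.40, adjusted p = 0.0184), without distal replicate 2 (adjusted p = 0.0342) and without proximal replicate 3 (adjusted p = 0.0133). The 8 endothelium genes had a median of -0.06 (camera adjusted p = 0.626), which was 0.20 without proximal replicate 3 and -0.14 without distal replicate 3. The 8 pericyte genes had a median of 0.44 (camera adjusted p = 0.197), and passed toward proximal without distal replicate 3 (median 0.88, adjusted p = 0.00215) and without proximal replicate 2 (median 0.66, adjusted p = 0.00619). Of these Vtn passed over the list alone (adjusted p = 0.00263, limma), and fry's test for change in either direction gave an adjusted p of 0.00492 for this list. The 5 adipocyte genes had a median of 0.11 (camera adjusted p = 0.744; 0.50 without distal replicate 3, which passed with an adjusted p of 0.0453), with Fabp4 at 4.98 and 15.0 against 0.220 and 2.21 FPKM. The 4 haemoglobin genes tested had a median of -0.09 (camera adjusted p = 0.744), and all were listed at 0 in proximal 2. Their median was 1.44 without proximal replicate 2 and -1.65 without proximal replicate 3, in fits that mix region with number. No seminal vesicle gene reached the minimum for testing. In the leukocyte, endothelium, Schwann cell, adipocyte and erythroid lists 0 genes passed over the list alone.

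**Figure D3:**
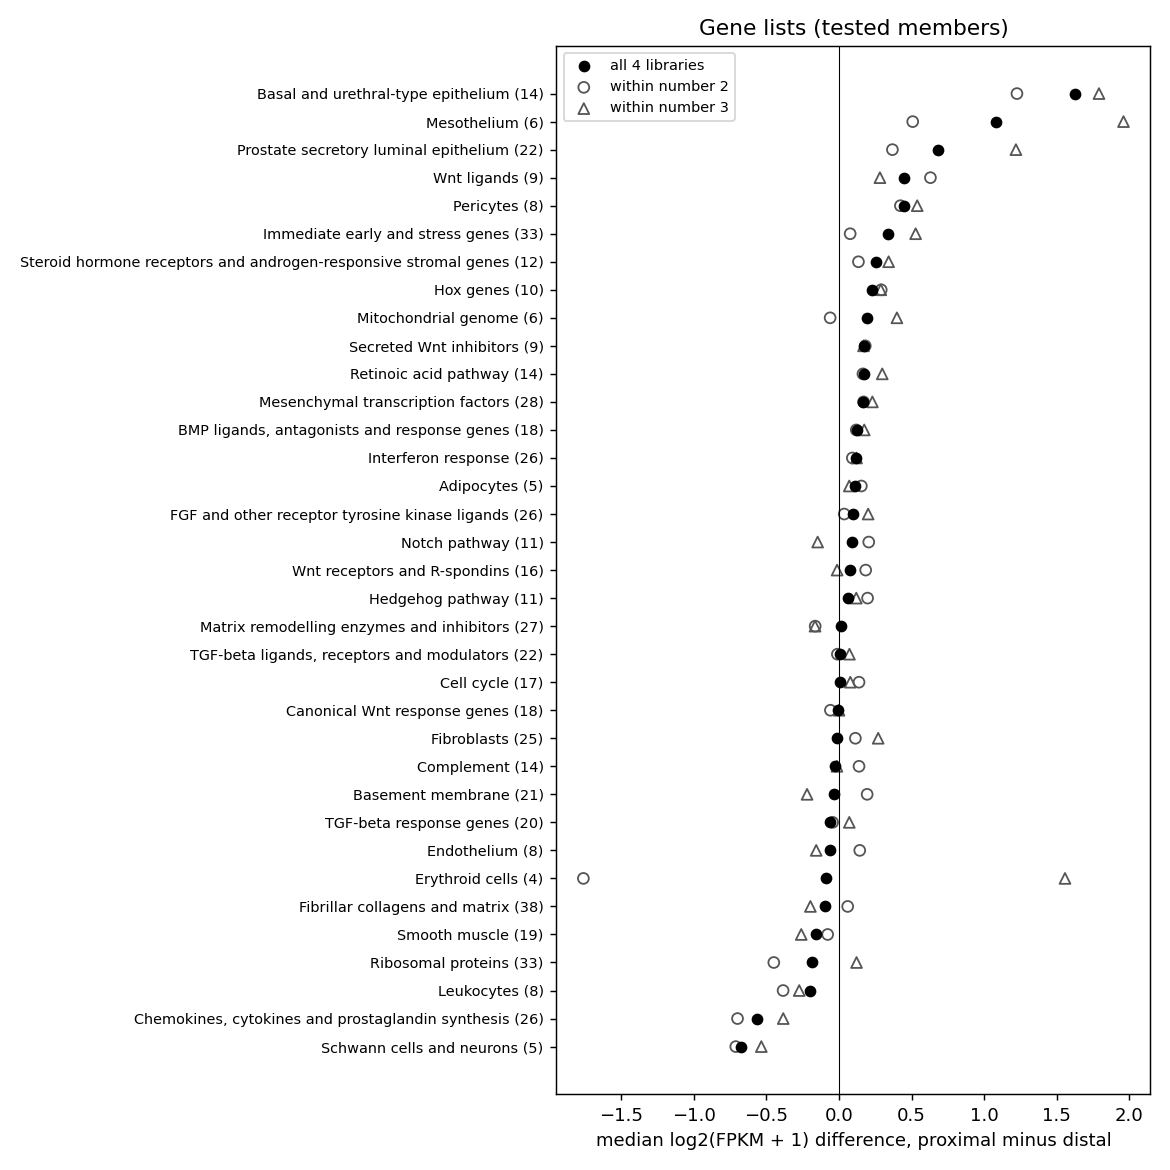
Median log2(FPKM + 1) difference between proximal and distal stroma for each of the 35 tested gene lists (tested members in brackets), over all 4 libraries (filled circles), within number 2 (open circles) and within number 3 (triangles). Over all 4 libraries, the basal and urethral-type epithelium list lies farthest to the proximal side at 1.62 and the Schwann cell and neuron list farthest to the distal side at -0.67.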

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

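With limma, the count of 0 called genes in each direction was the same under every scaling, pseudocount, filter and variance setting run, with transcripts as features, and with 2 settings chosen after seeing the data (genes listed at 0 left out, unnamed transcripts kept). It moved when 1 library was left out, to between 21 and 32 genes higher in proximal and between 3 and 30 genes higher in distal stroma; the lone library of a region was then assumed to vary like the others, and the cause was not tested. With the replicate block, 300 genes were higher in proximal and 140 genes higher in distal stroma, 440 genes in all. These included all 24 of the genes named for the smallest p, which were picked from the same libraries, so that was partly built in. The leukocyte list was then called too (adjusted p = 0.0402), and no other list call changed. The libraries numbered 2 deviated together from their region means (correlation 0.816 across genes), but no label says that a number marks a shared animal or day, so these counts are an alternative only. In simulated data with spread shared by number, the replicate block recovered 48.8% of 2-fold and 98.4% of 4-fold changes, with 10.7% of its calls false. With independent spread it recovered 0% of 2-fold, 0.3% of 4-fold and 18.8% of 16-fold changes, with 15.8% of its calls false.

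Genes at an unadjusted p under 0.05, 252 with higher proximal and 102 with higher distal values, numbered 743 and 196 with no filter (more genes tested), 129 with higher proximal values at a minimum of 5 FPKM (fewer genes tested), 1736 and 711 with the replicate block, 184 with higher distal values with transcripts as features, and 143 to 321 and 57 to 265 with 1 library left out. The number of called lists, 4, went to between 7 and 13 lists with 1 library left out, and to 0 with an estimated correlation and 0 with fry. Camera's direction against other genes differed in 50 of 522 list values, 34 of them with 1 library left out, and in 7 of the 50 the list was called in one of the fits compared. With no filter this was the Schwann cell and neuron list (median 0.0569). With 1 library left out it was the interferon list without distal replicate 2 or proximal replicate 3 (medians over the 4 such fits from -0.7787 to 0.8958), luminal epithelium (0.0571 to 1.1205) and basal and urethral-type epithelium (0.8081 to 2.5908) without proximal replicate 3, and erythroid genes (-1.6487 to 1.4447) and ribosomal proteins (-0.4602 to 0.0953) without proximal replicate 2. A fit with 1 library left out keeps only 1 number in 1 region, so its region difference takes in part of the difference between numbers. That difference, number 3 minus number 2, had a median of 1.445 for interferon, 1.608 for basal and urethral-type epithelium and 0.985 for luminal epithelium genes. It was 1.434 for erythroid and 0.239 for ribosomal protein genes. The cause of the change with no filter was not tested. Of 1690 values of 118 named or listed genes, 21 changed sign, 18 of these with 1 library left out. The missing total of fragments limits what can be said of genes near 1 FPKM.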

Other observations

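The tests of depth, of other cell types and of carried-over epithelium were chosen after the result was seen. Several lists had other levels in the libraries numbered 3 than in those numbered 2, averaged over the regions and without a test. The median log2 difference was 1.61 for basal and urethral-type epithelium, 1.44 for interferon response, 1.43 for erythroid and 1.31 for mesothelium genes, and -1.29 for Wnt ligands, -1.24 for canonical Wnt response genes and -1.10 for Hox genes. The interferon-induced gene Ifit2 stood at 153 and 74.97 FPKM in distal 3 and proximal 3 and at 22.7 and 19.9 FPKM in distal 2 and proximal 2. Genes listed at 0 in both libraries of one kind and at 3 FPKM or more in the other 2 numbered 10 for distal, 1 for proximal, 9 for number 2 and 29 for number 3.

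The first pattern is that libraries with the same number resembled each other more than libraries of the same region. Splitting the 4 libraries by number gave 2127 called genes with limma, against 0 by region and 0 for the crossed split, which restates the same likeness of the same libraries and is no separate evidence. Coverage per FPKM was higher in number 3 within both regions, by 0.667 in distal and only 0.158 in proximal libraries. The number difference should then be smaller in proximal libraries, with an expected slope on the distal one of 0.268; the slope across genes, which are not independent, was 0.958. This argues against depth as the whole cause, as far as coverage per FPKM measures it. It also assumes that an effect of depth scales with the log of that coverage, which was not shown. Length and GC content are argued against, because the number differences of distal and proximal libraries still correlated at 0.818 across genes after that trend was removed. Noise of genes near the floor is argued against as well, with a correlation of 0.836 among 3038 genes with a mean of at least 20 FPKM. A shared day, animal group or preparation stays open, as no label gives one, and no biological explanation was tested.

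The second pattern is the higher level of basal and urethral-type epithelium genes in proximal libraries. A lower share of stromal cells would raise markers of every other cell type alike. The list medians did not move alike. They were 1.08 for mesothelium, 0.68 for luminal epithelium, 0.44 for pericytes and 0.11 for adipocytes. They were -0.064 for endothelium (SD 0.199 over its members), -0.20 for leukocytes and -0.67 for Schwann cells and neurons. All 5 tested genes of the last list, of 22 listed, had higher distal values. The gate against lineage markers may also remove leukocytes and endothelium, so the Schwann list weighs most here. Its median was 0.0569 with no filter. The comparison therefore cannot decide for or against a lower share of stromal cells, and a rise of epithelium or mesothelium alone stays open. Epithelial cells carried through the sort are a candidate source: 7 genes shared by epithelia had a median difference of 0.763 within number 2 and 2.02 within number 3, with Krt8 at 68.8 and Krt18 at 64.0 FPKM in proximal 3, and with Cd24a at 54.6 FPKM in proximal 3 against 19.1 FPKM in distal 3, although the gate was set against CD24 and CD49f and Krt18 and Cd24a were lower in proximal 2 than in distal 2. All of the 7 genes but Cldn4 also belong to the luminal epithelium list, and Krt8 and Krt18 to the mesothelium list. They were chosen after the result was seen, so their median is no separate evidence. Expression of the epithelial genes in proximal stromal cells stays open and was not tested.

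The third pattern is the 8 named genes with higher proximal values that were above 0 in every library. Their median log2 ratio of proximal 3 to proximal 2 was 0.642, against 2.40 for the epithelial list. Because these genes were picked for a small p, which needs proximal libraries that agree, this difference was partly built in, and carried-over epithelium and a difference between the stroma of the regions cannot be told apart by it. The 8 genes include the near-identical copies Sprr2a1 and Sprr2a2. Among the named genes with higher distal values, Crym and 9530003J23Rik belong to the luminal epithelium list, and carried-over epithelium was not tested for them.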
